A study of Mus musculus with 5 samples.

How the data were processed

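Liver RNA from db/db mice was sequenced in 5 samples, 3 from vehicle-treated and 2 from SR4-treated mice. Per the labels' protocols, RNA was extracted with the RNeasy Mini kit, and libraries were made from 500 ng of total RNA with a TruSeq RNA V2 kit, which does not keep the strand. The submitters' processing notes name TopHat2 2.1.1, Partek and the mouse build GRCm38 (mm10). The counter, the gene annotation and any filter are not given in the sources used here. Samples were grouped by their treatment label. The db/db genotype comes from the series' design text.

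The deposited signal values were gene read counts that had been adjusted to 1 library size, as shown by the values themselves. Each of the 5 columns summed to 25494249 within 0.0012%, and most values were not whole. Low values followed the quantile adjustment of edgeR's equalizeLibSizes, applied per group with a common dispersion of 0.0767. This adjustment was inverted to recover reads, with the library sizes and dispersion fitted from 20 patterns of low counts. Adjusting the recovered reads again returned the deposited values within 3.2e-10%, which shows only that the inversion converged. Of 37771 recovered values from 1 to 1000 reads, 85.3% were whole within 0.02 reads, and the rest were fractions of a read. Recovered totals ran from 22878374 to 28113096 reads. On simulated counts put through the same adjustment, 100% of counts came back within 0.02 reads.

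The table held 11065 rows. In 17 rows, with 0.18% of counts, the gene symbol had been replaced by a calendar date; they were left out of all tests. Of 11048 symbols, 10942 were matched to GENCODE M21 (GRCm38), which gave the coordinates. All genes whose coordinates are printed are annotated there as protein-coding. Lists were matched by symbol, with older symbols looked up among RefSeq synonyms.

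The test fixed before the data were examined was edgeR's quasi-likelihood test on counts. Because the values were not counts, the main test was instead limma on log2(value + 1), with values divided by TMM factors, a pseudocount of 1, genes kept at 10 or more in at least 2 libraries, and empirical Bayes with a mean trend and robust shrinkage. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. edgeR, DESeq2 and limma-voom were run on recovered reads rounded to whole numbers, as alternatives. Normalised counts are deposited values divided by the TMM factor. Gene lists (42 fixed, 35 with at least 5 measured genes) were tested with camera at a preset correlation of 0.01, on the same log2 values in place of voom values. Camera with an estimated correlation and fry stand beside it. Camera called 23 lists, 0 of which passed with an estimated correlation (smallest adjusted p = 0.277) and 1 of which passed fry's directional test; fry's test for change in either direction passed for 15 of these and for 8 lists that camera did not call.

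On simulated counts, limma recovered 19% of 100 2-fold and 96% of 99 4-fold genes among 10542 tested, with 8.1% of its calls false. The simulated dispersions lay on average below the fitted common dispersion of 0.0767, so these rates may be better than those in the data. The list test called the 1 list raised 1.5-fold and 0 of 40 unchanged lists. Since the simulated genes varied independently, this does not show how often lists of correlated genes are called falsely.

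Genes were named by a rule fixed before the data were examined. Rule A took genes that passed, had both SR4 libraries outside the vehicle range and a mean CPM of 1 or more, and kept the 15 largest changes in each direction, without predicted or unnamed genes and antigen receptor segments. Rule B took up to 4 passing members of each list with the smallest p, or 2 that did not pass. Rule C added Alb and Lepr. This gave 86 genes, 49 of which passed; 1 that did not pass is not reported here. The floor for a count of 0 was 3 reads per library. Intervals are 95% exact Clopper-Pearson intervals on recovered reads, and they and the floor cover counting error only.

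Alternatives fixed beforehand were DESeq2, limma-voom, RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 2 libraries, no robust shrinkage, the replicate number as a block, and each library left out. Those chosen after seeing the data were edgeR on recovered reads, equal totals only, and pseudocounts of 0.5 and 10. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.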

Results

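RNA sequencing measured gene expression in livers of db/db mice, an obese and diabetic strain with a defective leptin receptor. The mice received vehicle or SR4 at 10 mg/kg by oral gavage for 5 weeks, after 1 week of acclimatization. SR4 is a compound that the series describes as a proton transporter activated by fatty acids. The vehicle group held 3 libraries and the SR4 group 2 libraries. The single comparison asked how SR4 changed liver expression, with lipid storage, mitochondria, energy balance and oxidative stress as the stated interests. The deposited values were gene read counts brought to a common library size of 25494249. The read totals recovered from them were 24307996, 26768092 and 22878374 for vehicle libraries 1, 2 and 3, and 28113096 and 26407519 for SR4 libraries 1 and 2. The labels do not say that each sample came from its own animal, so p-values measure only the spread between these samples, which may be technical. Normalised counts below are per library of that common size, given as mean ± SD with n = 3 for vehicle and n = 2 for SR4. Fold changes are on the log2(value + 1) scale, which understates the change of low genes.

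In the SR4 livers 10 of 20 de novo lipogenesis genes were lower, and the 2 metallothionein genes and 3 of 22 female-biased liver genes were higher, at a limma adjusted p under 0.05. Elovl6, an enzyme that lengthens fatty acids (chromosome 3, 129532355 to 129638495, GRCm38), fell 5.03-fold from 20880 ± 1460 to 4161 ± 485 normalised counts. The metallothionein Mt2 (chromosome 8, 94172664 to 94173568) rose 5.55-fold from 1782 ± 238 to 9841 ± 349. Cux2, a transcription factor expressed mainly in female liver (chromosome 5, 121856366 to 122050102), rose 38.7-fold from 19.8 ± 10.5 to 715 ± 39.8. Cidea, a lipid droplet protein (chromosome 18, 67343604 to 67367785), fell 20.9-fold from 3034 ± 674 to 167 ± 125 (log2 fold change -5.23 without SR4 1 and -3.54 without SR4 2). The adjusted p-values from limma were 0.0058 for Elovl6, 0.00579 for Mt2, 0.0264 for Cux2 and 0.0364 for Cidea.

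Of 10542 genes tested with limma, 2253 had an unadjusted p under 0.05, the background for the unadjusted counts of list members below. After adjustment 139 genes changed at the threshold of 0.05, with 46 higher and 93 lower. The SR4 libraries lay outside the range of the vehicle libraries for all 139, as they did for 41.6% of all genes tested, against 20% by chance. The change was at least 2-fold for 34 of the higher and 71 of the lower genes. The count depended on single libraries and on the tool: it was 8 without vehicle 2, 5 without vehicle 3 and 7 without SR4 2, and 1058 with DESeq2, 53 with edgeR and 44 with limma-voom on recovered reads. Scaled to equal totals alone, 37 genes were higher and 135 lower, with the median of all genes moved from -0.01 to -0.13. Of 49 genes named here as passing, 31 passed without vehicle 1, 3 without vehicle 2 and 4 without vehicle 3. All 49 kept their direction with any 1 library left out. That was nearly fixed beforehand, since both SR4 libraries lay outside the vehicle range for each of them. Elovl6, Mt2 and A4gnt passed in each of the 17 alternative analyses.

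**Figure D1:**
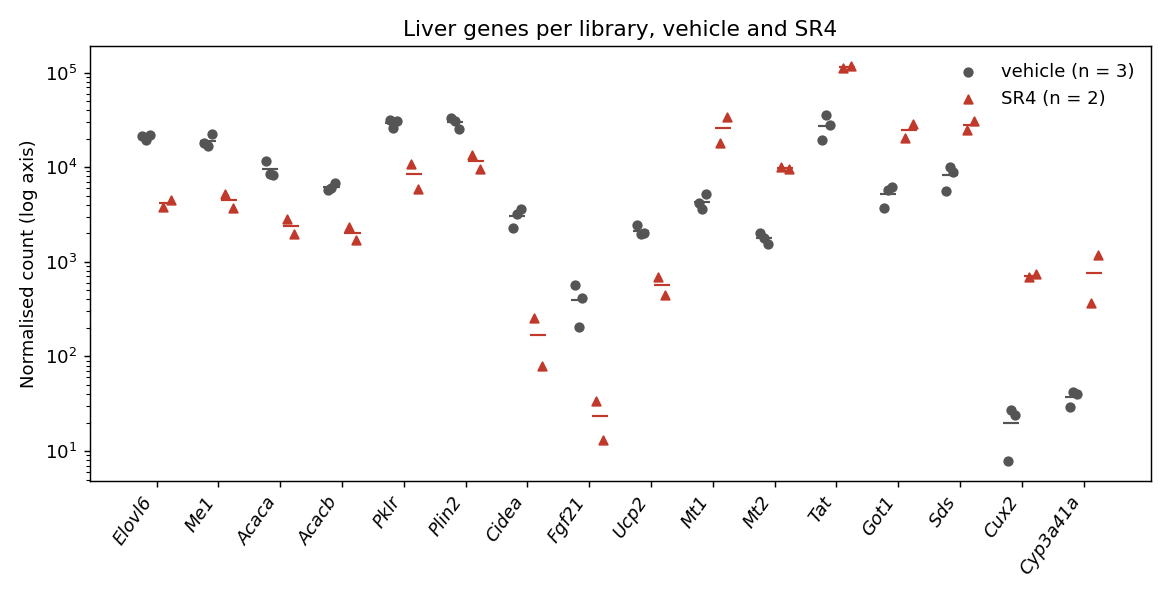
Normalised counts (log axis) of 16 named genes in each of the 3 vehicle libraries (grey circles) and 2 SR4 libraries (red triangles), with horizontal bars at the group means. The SR4 libraries lie below the vehicle libraries for the genes from Elovl6 to Ucp2 and above them for the genes from Mt1 to Cyp3a41a.

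Gene lists were fixed before the data were examined and tested with camera. De novo lipogenesis was the list with most falling members. Of 20 members, 10 fell and 0 rose over all genes tested, and 13 fell adjusted over the list alone. Beside Elovl6, Me1, which makes NADPH, fell 4.32-fold from 19060 ± 3110 to 4447 ± 1100 normalised counts. Acaca and Acacb, the acetyl-CoA carboxylases, fell 3.96-fold and 3.07-fold, Acaca from 9479 ± 1940 to 2394 ± 579 and Acacb from 6164 ± 547 to 2029 ± 466. Fasn, the fatty acid synthase, and Scd1, the stearoyl-CoA desaturase, were singled out after their values were seen. Fasn fell 4.99-fold from 89970 ± 9330 to 18870 ± 8140, and Scd1 fell 3.85-fold from 797700 ± 161000 to 204700 ± 12900. Srebf1 and Mlxipl, transcription factors of this pathway also singled out afterwards, did not pass (limma adjusted p = 0.536 and 0.259). Srebf1 had 12060 ± 1930 and 16330 ± 7750 normalised counts, and Mlxipl 4409 ± 1410 and 2794 ± 744. The list had a median log2 fold change of -1.39 and was called lower (camera adjusted p = 9.8e-12; adjusted p = 0.277 with an estimated correlation). It was also the 1 list that passed fry (adjusted p = 0.0188).

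Triglyceride synthesis and lipid droplet genes included 3 that fell and 0 that rose among 26, and 10 that fell and 3 that rose adjusted over the list alone. Besides Cidea these were Plin2, a lipid droplet coat protein, from 29670 ± 4100 to 11630 ± 2750 normalised counts, and Mogat1, a monoacylglycerol acyltransferase, from 510.5 ± 87.6 to 231.1 ± 8.39. As a list they were called lower, with a median of -0.54 (camera adjusted p = 0.00106; adjusted p = 0.445 with an estimated correlation). Cidea was also the 1 member that fell among the 3 adipocyte markers measured, too few for a list test. Pnpla5, a lipase of the patatin family, had 130 recovered reads over the 3 vehicle libraries and 2 over the SR4 libraries, a ratio of 44.1 (95% exact interval 12 to 368, counting error only). In lipoprotein secretion, 1 of 17 genes fell, Pltp, the phospholipid transfer protein, from 3947 ± 1060 to 1084 ± 251, and 5 rose and 5 fell adjusted over the list alone. That list was not called (camera adjusted p = 0.919), and its median of 0.04 and mean of -0.22 differed in sign; the median was -0.07 under scaling to equal totals and ran from -0.04 to 0.13 with 1 library left out.

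Glycolysis and glycogen genes included 2 that fell among 22, and 4 adjusted over the list alone. Pklr, the liver pyruvate kinase, fell 3.65-fold from 29320 ± 3140 to 8374 ± 3500 normalised counts, and Gpi1, glucose-6-phosphate isomerase, fell 2.30-fold from 9342 ± 1440 to 4025 ± 179. The glycolysis list was called lower, with a median of -0.36 (-0.58 without SR4 1 and -0.19 without SR4 2; camera adjusted p = 6.96e-04; adjusted p = 0.445 with an estimated correlation). In gluconeogenesis and glucose output, 3 of 17 genes rose, and 6 adjusted over the list alone. They were the amino acid enzymes Got1, from 5165 ± 1300 to 24530 ± 5960, Tat, from 27520 ± 7990 to 114800 ± 3070, and Sds, from 8167 ± 2320 to 27730 ± 4590. Of the 17 genes, 11 had a fitted change above 0 and 6 below. Pck1 and G6pc, singled out after their values were seen, went opposite ways. Pck1 had 57050 ± 16200 and 138100 ± 13500, and G6pc 14310 ± 2340 and 10140 ± 3330. Neither passed over all genes (limma adjusted p = 0.0687 and 0.266). The glucose output list was called higher, with a median of 0.22 (0.07 without vehicle 3 and 0.102 with equal totals; camera adjusted p = 0.0195; adjusted p = 0.445 with an estimated correlation). Its call was lost without SR4 1 (camera adjusted p = 0.165, within 0.00297 to 0.165 over 12 alternatives). In insulin and growth hormone signalling, 1 of 18 genes rose and 1 fell, and 3 rose and 1 fell adjusted over the list alone. Igfbp2, an IGF-binding protein, rose 2.46-fold from 765.5 ± 192 to 1844 ± 51.3, and Pik3r1, a regulatory subunit of PI3-kinase, fell 1.60-fold from 2030 ± 82.3 to 1268 ± 130. The list mixes receptors and effectors with inhibitors such as Socs2 and Socs3, so its direction does not give that of signalling. Insr, Irs1 and Igf1 had log2 fold changes of 0.026, -0.023 and 1.02, and Socs2 and Socs3 1.28 and 0.84. None of these passed over all genes. That list was called higher with a median of 0.26 (0.144 with equal totals; camera adjusted p = 0.0143; adjusted p = 0.445 with an estimated correlation).

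No gene of oxidative phosphorylation or of mitochondrial fatty acid oxidation passed over all genes, while citrate synthase and Ucp2 fell. None of the 77 nuclear-encoded oxidative phosphorylation genes passed the limma test, over all genes or adjusted over the list alone, and their median was 0.17 (0.0527 with equal totals). Ndufa8 had 3186 ± 220 and 2294 ± 212 normalised counts in vehicle and SR4, and Sdhb 7160 ± 680 and 10370 ± 2030. As a list they were called higher (camera adjusted p = 6.87e-04; adjusted p = 0.711 with an estimated correlation). The direction turned without SR4 2, with a median of -0.01 (0.35 without SR4 1) and a camera adjusted p of 0.476, within 3.84e-11 to 0.476 over 12 alternatives. None of the 21 mitochondrial fatty acid oxidation genes passed over all genes, and 1 rose adjusted over the list alone. Acad10 had 1656 ± 90.2 and 2436 ± 0.594, and Echs1 8902 ± 383 and 12000 ± 686. That list had a median of 0.09 (0.04 without SR4 1) and was called higher (camera adjusted p = 0.0430; adjusted p = 0.445 with an estimated correlation). Its median was -0.02 under scaling to equal totals, where the call was lost (camera adjusted p = 0.107), as it was without vehicle 1, vehicle 3 or SR4 1 (camera adjusted p = 0.0828, 0.0926 and 0.168, within 0.0217 to 0.168 over the alternatives). With limma, 9 of the 77 and 4 of the 21 genes had an unadjusted p under 0.05. Neither share was above that of all genes, 2253 of 10542. DESeq2 called 2 of each list, and edgeR and limma-voom called 0. Cs, citrate synthase, fell 1.84-fold from 5430 ± 471 to 2954 ± 347, as the 1 member of 17 TCA cycle genes that passed, with 3 adjusted over the list alone. Ucp2, a mitochondrial carrier of the uncoupling protein family, fell 3.81-fold from 2134 ± 254 to 570.2 ± 176, as the 1 of 23 genes of mitochondrial biogenesis, dynamics and uncoupling that passed on either adjustment. Neither list was called (camera adjusted p = 0.491 for the TCA cycle and 0.0903 for biogenesis).

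PPAR-alpha targets outside mitochondrial oxidation included 2 that fell and 0 that rose among 22, and 5 that fell and 1 that rose adjusted over the list alone. Fgf21, a liver hormone (chromosome 7, 45613886 to 45615490), fell 16.6-fold from 398.2 ± 185 to 23.4 ± 14.6 normalised counts (log2 fold change -4.71 without SR4 1 and -3.40 without SR4 2), and Acot2, a mitochondrial acyl-CoA thioesterase, fell 1.95-fold from 832.4 ± 130 to 424.5 ± 40.1. The list was not called (median -0.24, -0.31 to -0.08 with 1 library left out, camera adjusted p = 0.151), but was called lower without SR4 1 (camera adjusted p = 0.0131, within 0.0131 to 0.412 over 12 alternatives). No gene passed among 24 of cholesterol synthesis and uptake, on either adjustment, and that list was not called (median -0.07, -0.184 with equal totals, camera adjusted p = 0.398). Without SR4 2 it was called lower (median -0.27, camera adjusted p = 4.75e-05, within 4.75e-05 to 0.570 over the alternatives), and without SR4 1 its median was 0.10. Its members with the smallest p were Fdps, with 6159 ± 1050 and 3388 ± 1010, and Pmvk, with 1530 ± 96.7 and 1155 ± 124. None of 23 bile acid genes passed on either adjustment. Akr1d1 had 6566 ± 1220 and 11940 ± 1810, and Abcg5 1887 ± 332 and 4658 ± 2040. The bile acid list was called higher with a median of 0.21 (0.13 to 0.35 with 1 library left out and 0.091 with equal totals; camera adjusted p = 0.0432; adjusted p = 0.525 with an estimated correlation), and the call was lost without vehicle 1, without SR4 1 and under the stricter filter (camera adjusted p = 0.1, 0.177 and 0.0723, within 0.0124 to 0.177). In limma 7 cholesterol and 9 bile acid genes had an unadjusted p under 0.05, DESeq2 called 2 and 4, and edgeR and limma-voom called 0.

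Both metallothioneins rose. Mt1, a zinc-binding protein next to Mt2 (chromosome 8, 94179082 to 94180327), rose 5.80-fold from 4330 ± 770 to 26160 ± 11500 normalised counts. Mt1 and Mt2, which are not enzymes, were the 2 that rose, on either adjustment, among 19 genes listed as other antioxidant enzymes. Reads of genes as similar as Mt1 and Mt2 can be split between them. The other 17 members did not pass, and 4 of the 19 had a fitted change below 0. That antioxidant list was called higher, with a median of 0.17 (0.28 without SR4 1 and 0.0512 with equal totals; camera adjusted p = 0.00839; adjusted p = 0.445 with an estimated correlation). Its call was lost without SR4 2 (camera adjusted p = 0.0667, within 0.00302 to 0.0667 over 12 alternatives). Cbr3, a carbonyl reductase, fell 10.4-fold from 571.8 ± 173 to 60.3 ± 42.6 (log2 fold change -4.15 without SR4 1 and -2.60 without SR4 2), the 1 member of 23 NRF2 target and glutathione genes that passed, while 6 fell and 2 rose adjusted over the list alone. The NRF2 list was called lower with a median of -0.25 (-0.39 without vehicle 2; camera adjusted p = 0.0293; adjusted p = 0.498 with an estimated correlation), and the call was lost without vehicle 1, without vehicle 3, without SR4 1 and under scaling to equal totals (camera adjusted p = 0.0504, 0.0926, 0.1 and 0.0956, within 0.00383 to 0.1). None of 8 NADPH oxidase and oxidant-producing genes passed on either adjustment. Txnip had 2969 ± 425 and 1617 ± 639, and Ncf4 36.7 ± 11.8 and 12.7 ± 5.18. That list was called lower with a median of -0.79 (-0.50 without SR4 2; camera adjusted p = 0.0430; adjusted p = 0.498 with an estimated correlation), and the call was lost without SR4 2 and under scaling to equal totals (camera adjusted p = 0.186 and 0.116, within 0.0137 to 0.186). The ER stress list of 22 genes and the ATF4 and mitochondrial stress list of 15 had no member that passed over all genes, and neither was called (medians -0.15 and 0.16, -0.265 and 0.0477 with equal totals, camera adjusted p = 0.164 and 0.919). The ER stress list was called lower without SR4 1 (camera adjusted p = 0.00131, within 0.00131 to 0.343 over the alternatives), and its median was 0.09 without SR4 2. Adjusted over the list alone, 0 ER stress genes passed, and 2 ATF4 genes rose and 1 fell. Atf6 had 2026 ± 199 and 1522 ± 139, Ern1 568.2 ± 106 and 411.3 ± 5.88, Vldlr 347.2 ± 46.4 and 582.9 ± 95.5, and Asns 14.98 ± 9.47 and 81.2 ± 20.8. The ATF4 list's mean of -0.12 differed in sign from its median, which was -0.27 without SR4 1. Unadjusted limma p-values were under 0.05 for 6 NADPH oxidase, 3 ER stress and 5 ATF4 genes, DESeq2 called 1, 0 and 4, and edgeR and limma-voom called 0.

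Of 22 female-biased liver genes, 3 rose and 0 fell over all genes tested, and 17 rose adjusted over the list alone. All 22 had a fitted change above 0, with a median of 1.67. They were called higher as a list (camera adjusted p = 1.9e-11), but not with an estimated correlation (adjusted p = 0.445) or with fry (adjusted p = 0.0707). Beside Cux2, Cyp3a41a, a cytochrome P450, rose 17.5-fold from 36.9 ± 6.81 to 767 ± 565 normalised counts (log2 fold change 4.96 without SR4 1 and 3.30 without SR4 2), and Atp6v0d2, a subunit of the vacuolar proton pump, rose 2.86-fold from 112.8 ± 17.3 to 326.6 ± 77.3. The Cyp3a41a value is uncertain, since reads can be shared with the near-identical Cyp3a41b. Male-biased liver genes went both ways, with 11 of 22 above 0 and 11 below, and were not called (median 0.06, -0.06 to 0.42 with 1 library left out, camera adjusted p = 0.405), and their median was -0.05 under scaling to equal totals, -0.0372 with no filter and -0.0345 with a pseudocount of 10. C8b, a complement component, was the 1 male-biased gene that rose, from 790.4 ± 210 to 2741 ± 441, and 3 rose and 4 fell adjusted over the list alone. In the CAR, PXR and AhR drug metabolism list, 2 of 28 genes rose, and 8 adjusted over the list alone. They were Cyp3a13, from 2580 ± 408 to 6039 ± 259, and Cyp1a2, from 9331 ± 2450 to 23790 ± 1610. Cyp2b10, Cyp3a11 and Cyp1a1, singled out afterwards, had log2 fold changes of 2.01, 0.42 and 0.07. They did not pass (limma adjusted p = 0.0836, 0.251 and 0.943). The drug metabolism list was called higher with a median of 0.63, and 0.41 without vehicle 1 (camera adjusted p = 5.6e-05, adjusted p = 0.445 with an estimated correlation). It shares Cyp2b9, Cyp2b13, Cyp3a16 and Cyp2a4 with the female-biased list, so these lists are not independent.

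Periportal hepatocyte genes were called higher with a median of 1.00 (camera adjusted p = 5.67e-07; adjusted p = 0.445 with an estimated correlation). Of 14 members, 1 rose over all genes, the serine dehydratase gene Sds, and 11 rose adjusted over the list alone. The amino acid and urea cycle genes Gls2, Hal, Ass1 and Cps1 had log2 fold changes of 1.81, 1.71, 1.47 and 1.175. Cyp2f2, Alb and Hsd17b13 lay near 0, at 0.183, 0.0932 and -0.0953. These members were singled out after their values were seen, and none of them passed over all genes. A shift of liver zones was not tested. Pericentral genes were not called (median -0.07, -0.35 to 0.08 with 1 library left out and -0.187 with equal totals, mean 0.02, camera adjusted p = 0.801), with 1 of 13 rising over all genes, Cyp1a2, and 1 rising and 2 falling adjusted over the list alone. General hepatocyte markers were called higher with a median of 0.22 (0.15 without vehicle 1 and 0.105 with equal totals; camera adjusted p = 0.00339; adjusted p = 0.445 with an estimated correlation), with 0 of 19 passing over all genes and 7 rising adjusted over the list alone. That call was lost without SR4 1 (camera adjusted p = 0.0548, within 7e-04 to 0.0548 over 12 alternatives). Of these markers 9 had an unadjusted limma p under 0.05, DESeq2 called 9, and edgeR and limma-voom called 0. Serpina1a, one of several near-identical copies, had 48780 ± 6070 and 87570 ± 5490 normalised counts, and Ass1 of the urea cycle 6009 ± 1790 and 16850 ± 7000. Alb had 1858000 ± 304000 and 1977000 ± 315000, a difference within the spread between replicates (limma adjusted p = 0.891), whose sign turned under scaling to equal totals.

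Macrophage and stellate cell markers were called lower as lists with the preset correlation but not with an estimated one (adjusted p = 0.469 and 0.498), and no single gene passed the all-gene limma test. Macrophage and Kupffer cell markers had a median of -0.94 (-1.33 without SR4 1 and -0.53 without SR4 2), and 7 of 19 fell adjusted over the list alone. The macrophage antigen gene Emr1 had 256.7 ± 59.5 and 133.1 ± 31.4 normalised counts, and Gpnmb 256.7 ± 203 and 26.8 ± 19.4. The camera adjusted p of macrophage markers was 2.1e-05 with the preset correlation. All 24 stellate cell and fibrosis genes had a fitted change below 0, with a median of -0.70 (-0.46 without SR4 2), and 0 passed on either adjustment. The collagen genes Col1a1 and Col1a2 had 1093 ± 466 and 341.2 ± 73.2, and 1270 ± 412 and 519.2 ± 92.4. Their camera adjusted p was 6.81e-06 with the preset correlation. Endothelial markers were not called (median -0.05, -0.165 with equal totals, camera adjusted p = 0.624), with 0 of 16 passing on either adjustment. Their call followed the SR4 library used: lower without SR4 1 (median -0.43, camera adjusted p = 0.00442) and higher without SR4 2 (median 0.27, camera adjusted p = 0.0168), with p within 0.00442 to 0.809 over 12 alternatives. Limma p-values were under 0.05 before adjustment for 9 macrophage, 8 stellate and 1 endothelial marker, DESeq2 called 8, 6 and 0, and edgeR and limma-voom called 0. Vwf had 260.9 ± 32.9 and 171.5 ± 24.4, and Gpr182 282.5 ± 36.1 and 370.6 ± 101. The 3 cholangiocyte, 1 neutrophil and 1 pancreas marker measured were too few for a list test, and 0 passed with limma at an unadjusted p under 0.05, DESeq2, edgeR or limma-voom. Spp1 had 1903 ± 1390 and 983.7 ± 379, S100a9 23.3 ± 11.5 and 11.3 ± 3.12, and Cela1 218.0 ± 74.6 and 178.1 ± 13.4. The 10 muscle markers lay under the low-value filter. Mitochondrially encoded transcripts, T, NK and B cell markers and Lepr were not analysed here.

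Of 4 immune and inflammatory lists, 3 were called lower and 1 higher with the preset correlation and 0 with an estimated one, in libraries where the median of macrophage markers was -0.94 (-1.33 to -0.53 with 1 library left out). In the interferon response, 1 of 24 genes fell, and 4 adjusted over the list alone. It was Ifi27l2a, from 107.2 ± 56.2 to 12.9 ± 3.19 normalised counts, and the list was called lower with a median of -0.38 (camera adjusted p = 5.79e-04; adjusted p = 0.445 with an estimated correlation). Antigen presentation had 0 of 15 genes passing on either adjustment, a median of -0.54 (-0.93 to -0.27 with 1 library left out) and a camera adjusted p of 0.00528 (adjusted p = 0.469 with an estimated correlation). Tap1 had 604.0 ± 54.6 and 434.7 ± 57.8, and H2-Q7 470.0 ± 65.3 and 257.8 ± 132. Inflammatory cytokines and chemokines had 0 of 16 passing on either adjustment, a median of -0.69 (-1.22 to -0.10 with 1 library left out) and a camera adjusted p of 0.0210 (adjusted p = 0.498 with an estimated correlation). Ccl2 had 60.1 ± 50 and 12.2 ± 5.91, and Cxcl14 93.5 ± 47.4 and 27.1 ± 3.10. Without SR4 2 both lists lost their call (camera adjusted p = 0.108 and 0.308, within 3.87e-04 to 0.108 and 0.00317 to 0.308 over 12 alternatives), as did the cytokine list under scaling to equal totals (camera adjusted p = 0.0887). The acute phase list was called higher with a median of 0.13 (0.02 to 0.39 with 1 library left out and 0.0121 with equal totals; camera adjusted p = 0.0293; adjusted p = 0.525 with an estimated correlation), with 0 of 22 passing over all genes and 1 rising adjusted over the list alone. Its call was lost without vehicle 3 or SR4 1 (camera adjusted p = 0.106 and 0.939, within 6.93e-06 to 0.939). At an unadjusted p under 0.05 limma gave 4 antigen presentation, 5 cytokine and 8 acute phase genes, DESeq2 called 0, 3 and 6, and edgeR and limma-voom called 0. Hamp and Hamp2, the hepcidin genes, had 6027 ± 2860 and 30650 ± 2800, and 5845 ± 3550 and 47340 ± 30200.

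Proliferation genes were called lower with a median of -1.44 (-1.99 to -0.74 with 1 library left out; camera adjusted p = 3.28e-05; adjusted p = 0.498 with an estimated correlation). Of 20 members, 19 had a fitted change below 0, and 8 fell and 1 rose adjusted over the list alone. The member that passed over all genes was Tk1, thymidine kinase, which rose 2.68-fold from 404.6 ± 87.6 to 1070 ± 88.4 normalised counts. Tk1 (chromosome 11, 117815526 to 117826092) overlaps Afmid (chromosome 11, 117825924 to 117839908) by 169 bases, so their reads may not be told apart there. Cell death and p53 targets were not called (median -0.25, camera adjusted p = 0.0592), with 0 of 14 passing on either adjustment. They were called lower without vehicle 2 or vehicle 3 (camera adjusted p = 0.0463 and 0.0329, within 0.0329 to 0.159 over 12 alternatives). Bax had 610.1 ± 118 and 386.3 ± 20.1, and Zmat3 240.1 ± 33.6 and 153.0 ± 14.6. The circadian clock list was not called (median 0.13, -0.01 to 0.36 with 1 library left out and 0.013 with equal totals, camera adjusted p = 0.0903), with 0 of 18 passing over all genes and 1 rising adjusted over the list alone. It was called higher without vehicle 3, without SR4 2 and under scaling to equal totals (camera adjusted p = 0.0171, 0.0433 and 0.0414, within 0.0171 to 0.274). At an unadjusted p under 0.05 limma gave 6 p53 and 4 clock genes, DESeq2 called 3 and 1, and edgeR and limma-voom called 0. Nfil3 had 290.3 ± 16.6 and 495.0 ± 70.1, and Cry2 994.0 ± 145 and 1422 ± 113. Erythroid markers were called lower with a median of -0.77 (camera adjusted p = 5.66e-04; adjusted p = 0.445 with an estimated correlation). Of 7 members, the beta-globin genes Hbb-bs and Hbb-b1 fell over all genes, from 2507 ± 285 to 1115 ± 123 and from 4460 ± 532 to 1950 ± 393, and 6 fell adjusted over the list alone. Globin reads can be shared between copies, and the members Hbb-bt and Hbb-b2 carried identical values. Haemoglobin genes took 0.0803%, 0.103% and 0.0745% of counts in the vehicle libraries and 0.0489% and 0.0367% in the SR4 libraries, and exact permutation of 3 against 2 libraries cannot give a two-sided p below 0.1.

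**Figure D2:**
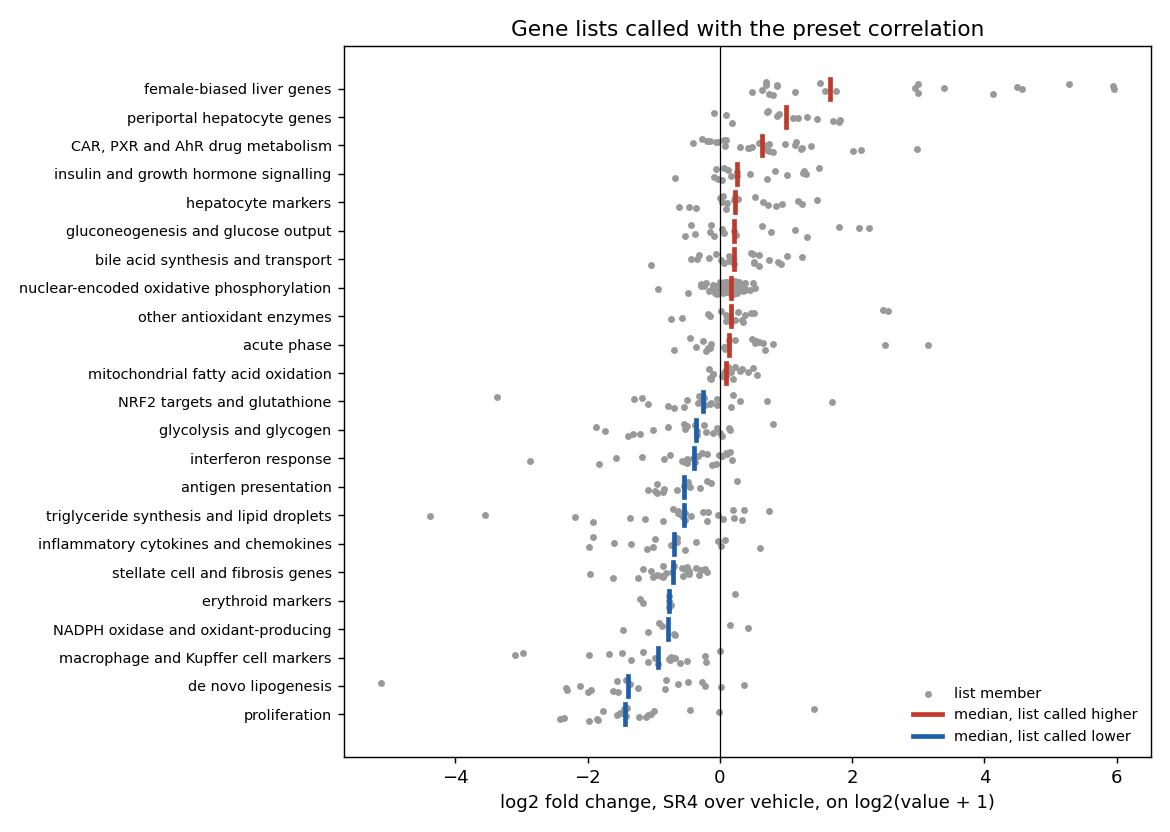
Log2 fold change of SR4 over vehicle (x axis, on log2(value + 1)) for the members of the 23 gene lists called by camera with the preset correlation. Grey points are genes and vertical bars are list medians, red for the 11 lists called higher and blue for the 12 called lower, from 1.67 for female-biased genes to -1.44 for proliferation; 0 of the 23 calls held with an estimated correlation.

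Other genes with the largest rises lay outside these lists. Afmid, an enzyme of tryptophan breakdown, rose 4.01-fold from 2574 ± 855 to 9918 ± 748 normalised counts, and Slc7a2, a transporter of cationic amino acids, rose 2.93-fold from 7957 ± 1270 to 23610 ± 6670. Zap70, a kinase of T cell receptor signalling, rose from 214.1 ± 40.3 to 842.5 ± 379. Sorbs3, encoding the adaptor vinexin, rose from 669.7 ± 136 to 2313 ± 3.22. Arl13b, a small GTPase of cilia, rose from 73.6 ± 11.8 to 244.0 ± 45.8, and Rnd1 from 120.1 ± 12.0 to 355.7 ± 136. Their limma adjusted p-values ranged from 0.0264 for Sorbs3 to 0.0489 for Rnd1.

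Among the largest falls, Hormad2, a meiotic chromosome protein, had 178 recovered reads over the vehicle libraries and 0 in both SR4 libraries. Against a floor of 3 reads per SR4 library, it was at least 19.9-fold lower, counting error only. Ephb2, an ephrin receptor, fell from 606.7 ± 513 to 8.81 ± 2.50 normalised counts, and A4gnt, a glycosyltransferase, fell 7.43-fold from 391.7 ± 54.4 to 51.7 ± 6.79 with a limma adjusted p of 0.00605. Kbtbd11 fell from 172.9 ± 73.1 to 16.6 ± 7.85, Cgref1 from 355.7 ± 88.6 to 43.0 ± 15.2, and Chrna4, a nicotinic acetylcholine receptor subunit, from 201.9 ± 92.3 to 24.0 ± 5.44. Spon2, a secreted matrix protein, fell from 520.4 ± 288 to 68.1 ± 13.6, and Cntnap1 from 543.9 ± 216 to 92.2 ± 10.6. Krt20, a keratin, fell from 98.0 ± 24.8 to 15.2 ± 0.140, and Slc16a13, a monocarboxylate transporter, from 99.8 ± 0.584 to 16.2 ± 2.72.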

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

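The alternatives with edgeR on recovered reads, equal totals and pseudocounts of 0.5 and 10 were chosen after seeing the data. The 139 genes changed became 1058 with DESeq2, 53 with edgeR and 44 with limma-voom on recovered reads. All 139 had the same sign in each alternative. Since both SR4 libraries lay outside the vehicle range for all 139, this was largely fixed beforehand. Under RLE and upper-quartile scaling, equal totals, both filters, both pseudocounts and no robust shrinkage, the count ran from 130 to 172. Leaving out 1 library gave 5 to 192 genes, with 5 without vehicle 3, 7 without SR4 2, 8 without vehicle 2, 108 without vehicle 1 and 192 without SR4 1; with 1 SR4 library left, that library is assumed to vary like the vehicle libraries. With the replicate block the count was 459. The groups share 2 numbers, whose libraries' deviations correlated at 0.17 and 0.11, fewer than 3 pairs, and no label ties a number to an animal. The 23 lists called became 0 with an estimated correlation and 1 with fry, 20 with equal totals (19 of the 23 kept), 24 with no filter and 22 with the replicate block (20 kept). Leaving out 1 library gave 20 to 24, but kept only 17 of the 23 without SR4 1, 18 without SR4 2, 20 without vehicle 1 or vehicle 3 and 23 without vehicle 2, as other lists came in. Ranges of list p-values over alternatives leave the replicate block out. With that block 3 of the 23 calls were lost, and the circadian clock and p53 lists were called (camera adjusted p = 0.0114 and 0.0256). Of the 49 named genes that passed, 25 passed with edgeR, 23 with limma-voom, 49 with DESeq2 and 46 with the replicate block. Among named genes and called lists, those that reversed included Alb, at -0.025 with equal totals, -0.0041 without vehicle 1 and -0.070 without SR4 1 (-0.070 to 0.26 over libraries left out), Cela1, at 0.022 without vehicle 1 (-0.43 to 0.022), and the oxidative phosphorylation list, at -0.0084 without SR4 2 (-0.0084 to 0.353). The median of the mitochondrial fatty acid oxidation list also turned, to -0.0242 with equal totals, where camera's direction stayed up. Of the lists not called, the cholesterol, lipoprotein, ER stress, ATF4, TCA cycle, male-biased, endothelial and pericentral lists changed direction in at least 1 alternative. The haemoglobin share differed by -0.0431 percentage points between SR4 and vehicle, and by -0.0571 without the 10 most abundant genes. The cause was not tested for any of these. At this depth and size, simulated 2-fold changes were recovered in 19% of genes, with dispersions set on average below the fitted 0.0767.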

Other observations

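The tests of explanations below were chosen after the results were seen, except the count of splits, and the 2 gene lists of the next paragraph were written after the data were seen.

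Genes of amino acid breakdown and the urea cycle were grouped after their values were seen, so no test of them as a list is given. Of 55 genes, 54 had a fitted change above 0, with a median log2 fold change of 0.83. Both SR4 libraries lay above all 3 vehicle libraries for 51 of them. Over all genes tested 4 rose with limma, Got1, Tat, Afmid and Sds. Agxt, which removes glyoxylate, had 4239 ± 1540 normalised counts in vehicle (SD, n = 3) and 19270 ± 6880 in SR4 (SD, n = 2), and Cps1, the first enzyme of the urea cycle, 53560 ± 19700 and 117300 ± 30000; neither passed over all genes. Of 9 genes of the pentose phosphate pathway and NADPH supply, likewise chosen afterwards, 4 fell and 0 rose over all genes tested, with a median of -0.82. The transketolase Tkt fell from 11360 ± 417 to 5554 ± 616. Prlr, the prolactin receptor, rose 2.84-fold from 2402 ± 595 to 6704 ± 1110 (limma adjusted p = 0.047). Since 13 of the 55 and 3 of the 9 genes stand in the fixed lists, these values are not independent of the report.

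Of 20 lipogenic genes 10 were lower with SR4 over all genes tested, and the list passed fry (adjusted p = 0.0188) but not camera with an estimated correlation (adjusted p = 0.277). The median of the de novo lipogenesis list was -1.39 or lower under 3 other scalings, so the choice among these does not account for the fall. That was nearly fixed beforehand, since scaling to equal totals moved the median of all genes only from -0.01 to -0.13. A single library does not account for the size of the fall either, since the median closest to 0 with 1 library left out was -1.25. The sign of that median was nearly fixed beforehand, since both SR4 libraries lay outside the vehicle range for 75% of members. A longer fast before collection of the SR4 animals stays open. It would raise PPAR-alpha targets, whose median was -0.243 (-0.314 to -0.0797 with 1 library left out). Their quartiles ran from -0.957 to 0.317, with 10 of 22 members above 0 and 12 below. Fgf21 was lower. Cyp4a10 had 10830 ± 4000 and 34710 ± 2690 normalised counts, and Pdk4 582.3 ± 293 and 158.2 ± 55.9, and neither passed over all genes. Cyp4a10, Cyp4a14 and Acot3 also stand in the female-biased list, so their values are not independent of that list. An effect of SR4 on fat synthesis may therefore be weighed beside a difference in food intake, which was not tested.

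All 22 female-biased genes had fitted changes above 0, of which 3 passed over all genes, and the list did not pass with an estimated correlation (adjusted p = 0.445) or with fry (adjusted p = 0.0707). Female livers among the SR4 libraries would lack Y-linked transcripts, yet the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 97.5% and 86.2% of the vehicle mean in SR4 libraries 1 and 2. The median of the list was 1.35 or more with any 1 library left out, which argues against 1 library as the source of its size. Its sign was nearly fixed beforehand, since both SR4 libraries lay outside the vehicle range for 81.8% of members. A shift of the whole sex programme, as a changed pattern of growth hormone may give, would also lower male-biased genes, whose median was 0.0569 with quartiles from -0.803 to 0.845, and -0.0621 to 0.419 with 1 library left out. A median of either sign and members going both ways leave that hypothesis open.

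Tk1 rose while the other 19 proliferation genes had fitted changes below 0. Tk1 and its neighbour Afmid start on opposite strands and share 83 exon bases in GENCODE M21, and the kit does not keep the strand, so reads of Afmid may have been counted for Tk1. A line of Tk1 on Afmid through the 3 vehicle libraries predicted 1099 and 1206 normalised counts of Tk1 in the SR4 libraries, where 1007 and 1132 were seen, -8.34% and -6.16% off the line. The line's slope of 10.2% is larger than the 2.35% of Afmid exon bases that are shared, so the line alone does not settle it. Shared reads and shared control from the common start region, with its 83 shared bases, cannot be told apart without read positions.

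Of the 10 splits of the 5 libraries into 3 and 2, the real one gave 139 genes and the highest other gave 1 (vehicle 3 with SR4 2). Only 1 of the 10 gave as many, and 10 splits are too few for a share under 0.05. The first principal component held 62.4% of the variance. Vehicle libraries 1, 2 and 3 lay at -40.3, -13.5 and -14.1 on it, and SR4 libraries 1 and 2 at 23.0 and 44.9.

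The table itself carried some traits of its making. The geometric mean of the 5 recovered library sizes was 0.518% above the common size, and 1 further library of 24844413 reads would give that size. Of 11065 rows, 165 were at 0 in all 5 libraries and 471 (4.26%) stayed under 10 in all 5, among them the 10 muscle markers. Alas2, an erythroid gene, had 2069 ± 364 normalised counts in vehicle (SD, n = 3) and 2442 ± 607 in SR4 (SD, n = 2), while the alpha-globin gene Hba-a1 had 7377 ± 1770 and 4320 ± 1020.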
